A study of Mus musculus with 4 samples.

How the data were processed

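Spleens of Cx3cr1gfp/+ C57BL/6 mice were digested with collagenase, CD11c-positive cells were enriched with magnetic beads, and cells with high CD11c were sorted by flow cytometry into the 4 subsets, per the labels' protocols. Total RNA was labelled with biotin and hybridised to Affymetrix Mouse Genome 430.2 arrays, on which several short oligonucleotides make up each probe set. All samples carry the label of no BMP4 treatment. The gates, the number of mice and whether cells were pooled are not given in the sources used here. The deposited values are intensity values per probe set (signal) made with MAS5, per the submitters' processing notes, and its version is not given in the sources used here. MAS5 corrects each probe for background and for its mismatch probe and scales each array as a whole. In the deposited table the signal is on a linear scale, and its mean after trimming 2% of probe sets at each end was 150.0 on all 4 arrays. Such scaling fixes the mean of an array, so a difference in the total RNA per cell cannot be seen. Detection calls were not used here.

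The table holds 45101 probe sets, of which 64 are controls. Through the platform's annotation 34945 probe sets have 1 gene symbol, 932 have several and 9160 have none, and only those with 1 symbol were named. Symbols were checked through Entrez identifiers against the mouse RefSeq gene table of assembly GRCm38.p6, in which 99.4% of the identifiers stand, and 0 symbols changed. The build behind the array annotation is not given in the sources used here, so no coordinates are printed. A gene was represented by its probe set with the highest mean log2 signal over the 4 arrays. Low MAS5 signals vary widely, so a floor was set at the 90th percentile, pooled over the arrays, of 127 probe sets for chemosensory receptors and hair keratin-associated proteins, genes not known to be expressed in spleen. It came to 55.7. On single arrays this percentile was 46.9 (CD8+CX3CR1+), 62.6 (CD8+CX3CR1-), 59.9 (CD4+) and 52.8 (DN). Some values above the floor thus lay within their own array's background, and folds against them are best read as bounds. Among these values were Spib (60.3) and C1qb (60) on the CD8+CX3CR1- array, and Tlr3 (59.2) and Sh3pxd2b (56.9) on the CD4+ array. Values under the floor were raised to it, a gene was detected if it lay above the floor on at least 1 array, and a difference with 1 array under the floor is given as a bound ("at least N-fold"), with no fold where both were under it. No other scaling was applied to the values.

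Samples were grouped by title, 1 array per group, and 6 pairs of arrays were compared, 3 of them as main comparisons. With 1 array per group no test is possible, and differences have no replicate check. A gene was called when its log2 difference was at least 2 (4-fold). The 23 gene lists were fixed before the data were examined, as were the comparisons, the floor, the naming rule and the alternatives, and cover plasmacytoid DCs, CD8 DCs, CD4 and CD11b DCs, other cells of the spleen, and antigen presentation, interferon, cell cycle and related functions. A list's shift is the median log2 difference of its detected members. It was set against the medians of 10000 random lists of the same size, drawn from detected genes in 20 bins of mean signal. This describes these arrays and is not a p-value. The spread of a gene's difference over its probe sets was taken as a measure of probe error, which does not cover the spread between mice or sorts.

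The genes named are the sort markers Cd8a, Cx3cr1, Cd4 and Itgax. They also include, in each main comparison, up to 4 members of each list with the largest differences, the 8 largest differences each way among genes above the floor on both arrays, and the 5 brightest bounds each way. For each subset, the 8 genes furthest above the other 3 arrays were named as well. Genes with RIKEN, Gm or LOC names were passed over in favour of the next gene. The gene families, and other genes named in the observations after the results, were chosen after their values were seen, except the markers of other spleen macrophages.

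The steps were tested on simulated pairs of arrays made from the mean profile of the 4 arrays over 12608 genes, with normal noise of the size of the probe set spread between the CD4+ and DN arrays (root mean square 0.50, log2). Of 200 genes changed by 2-fold, 2% passed the 4-fold threshold, as did 86% at 8-fold and 97.5% at 16-fold, with 0, 0 and 2 unchanged genes past it. Of 100 unshifted lists of 15 genes, 7 lay outside the central range, and 100 of 100 lists shifted by 2-fold lay above it. The simulated noise had the same size at every signal level and was independent between genes. It held no spread between mice or sorts. The simulated counts therefore give no rate of false calls for the real arrays. The alternatives were quantile normalization, scaling to an equal median, a floor at the 75th or the 95th percentile, and no floor. Another took the mean over a gene's probe sets. Another left out probe sets with the suffixes _x, _s and _a, which can match several transcripts. For lists, a further one left out genes that stand in several lists. Computations used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.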

Results

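Gene expression was profiled in 4 subsets of dendritic cells (DCs) sorted from mouse spleen, with 1 Affymetrix array per subset. The mice carried a green fluorescent protein gene in place of 1 copy of Cx3cr1 (Cx3cr1gfp/+, C57BL/6 background), so that cells in which the promoter of this chemokine receptor gene is active can be seen by their fluorescence. The subsets were CD8+CX3CR1+ DCs, CD8+CX3CR1- DCs, CD4+ DCs and DN DCs, where DN is the usual abbreviation in this field for cells with neither CD4 nor CD8. With 1 array per subset there were no replicates, so no value below carries a standard deviation or a p-value, and each difference describes 2 arrays rather than 2 populations of mice. The number of arrays limits the precision. Values are MAS5 signal on a linear scale, and a difference was called when it was at least 4-fold. Of 18193 named genes, 12608 lay above the floor of 55.7 on at least 1 array. The share of probe sets above the floor was 41.7% on the CD8+CX3CR1+ array, 41.0% on the CD8+CX3CR1- array, 47.6% on the CD4+ array and 42.5% on the DN array. The CD4+ array also had the highest 3'/5' signal ratio of the Gapdh control probe sets, a ratio that rises as RNA integrity falls. It was 11.8 against 8.98, 8.33 and 7.56 on the CD8+CX3CR1+, CD8+CX3CR1- and DN arrays. The beta-actin ratio was also highest on the CD4+ array, at 2.86 against 2.32, 1.79 and 2.23 in the same order.

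The transcripts of the sort markers went with the sample titles. Cd8a had a signal of 2530 on the CD8+CX3CR1+ array and 4742 on the CD8+CX3CR1- array, against a value under the floor on the CD4+ array and 130 on the DN array. Cx3cr1 was 894 on the CD8+CX3CR1+ array and 97.3 on the CD8+CX3CR1- array, with 275 on the CD4+ array and 258 on the DN array. Cd4 reached 564 on the CD4+ array, while it was 93.3 on the CD8+CX3CR1+ array, 93.9 on the DN array and under the floor on the CD8+CX3CR1- array. Itgax, which encodes the CD11c chain used for enrichment, lay between 3271 and 6415 on all 4 arrays. In the sample labels, the field for the DC type disagrees with the title for the arrays titled CD8+CX3CR1- and DN. Groups were taken from the titles, with which the Cd8a, Cx3cr1 and Cd4 values go.

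**Figure D1:**
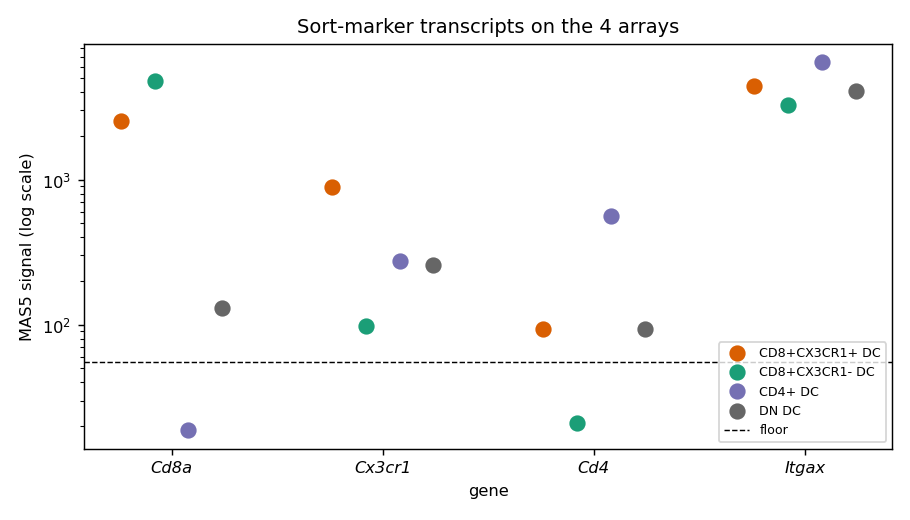
MAS5 signal (log axis) of the sort-marker genes Cd8a, Cx3cr1, Cd4 and Itgax, with 1 point for each of the 4 arrays and a dashed line at the floor of 55.7. Cd8a is high on both CD8+ arrays (2530 and 4742), Cx3cr1 is highest on the CD8+CX3CR1+ array (894) and Cd4 on the CD4+ array (564).

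Across the 12608 detected genes, the CD8+CX3CR1+ profile lay closer to the CD4+ and DN profiles than to the CD8+CX3CR1- profile. Its Pearson correlation was 0.960 with the DN array, 0.941 with the CD4+ array and 0.908 with the CD8+CX3CR1- array, and its Spearman correlation was 0.927, 0.893 and 0.871 in the same order. The lowest Pearson correlation of the 6 pairs, 0.894, was between the CD8+CX3CR1- and CD4+ arrays (Spearman 0.840), and the CD4+ and DN arrays correlated at 0.952 (Spearman 0.898). These correlations are across genes, which are not independent replicates. Without a floor, the CD8+CX3CR1+ array had a Pearson correlation of 0.869 with the DN array. It was 0.844 with the CD4+ array and 0.845 with the CD8+CX3CR1- array, with signals under the floor entering as they are. That the CD8+CX3CR1+ array lay closer to the CD4+ array thus rests on the use of a floor, though not on its height. With the floor at the 75th percentile these correlations were 0.936 and 0.916, and at the 95th percentile 0.939 and 0.896. By the number of genes at least 4-fold apart, the closest pair was CD4+ and DN, with 32 genes, rather than CD8+CX3CR1+ and DN, the pair with the highest correlation. The CD8+CX3CR1- array differed by 355 genes from the CD8+CX3CR1+ array, 376 from the CD4+ array and 255 from the DN array. The CD8+CX3CR1+ array differed from the CD4+ array by 97 genes, 50 higher and 47 lower, and from the DN array by 52 genes, 35 higher and 17 lower. Which pair was closest by these counts rested on the floor. With the floor at the 75th percentile, CD4+ and DN (50 higher, 39 lower) and CD8+CX3CR1+ and DN (57 and 31) were about equally close. Without a floor, CD8+CX3CR1+ and DN were the closest pair (1462 and 1350, against 1992 and 1218 for CD4+ and DN). Of the 376 genes that separated the CD8+CX3CR1- and CD4+ arrays, 297 (79.0%) had a signal on the CD8+CX3CR1+ array nearer, on the log2 scale, to that of the CD4+ array, as had 318 (84.6%) on the DN array. This last count was chosen after the data were examined.

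CD8+CX3CR1+ and CD8+CX3CR1- DCs, which both carry surface CD8, were compared to see how far their profiles differ. The CD8+CX3CR1+ array was at least 4-fold higher for 210 genes and at least 4-fold lower for 145. Cd8a was 1.87-fold lower on the CD8+CX3CR1+ array, with log2 differences of -0.98 to 0.53 at its 4 other probe sets above the floor, and Cx3cr1 was 9.18-fold higher. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, was 43.9-fold higher on the CD8+CX3CR1+ array (4728 against 108), Fcer1g, the common gamma chain of Fc receptors, 29.4-fold, and the colony-stimulating factor receptor gene Csf1r 22.7-fold. The other genes among the 8 largest differences in this direction were the glucose transporter gene Slc2a3 (37.9-fold), Dennd3 (29.5-fold), the Ets-family transcription factor gene Spib (25.8-fold), the oxysterol receptor gene Gpr183 (22.8-fold) and Klrd1, which encodes CD94 (22.3-fold). The brightest genes that lay under the floor on the CD8+CX3CR1- array were S100a4, a calcium-binding protein gene at least 161-fold higher on the CD8+CX3CR1+ array, Sox4 (at least 33.4-fold), Klra17 (at least 27.3-fold), Adam11 (at least 25.9-fold) and Cd209d (at least 24.0-fold).

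In the other direction, Rab7b, a small GTPase of late endosomes, was 38.5-fold lower on the CD8+CX3CR1+ array (82.9 against 3191). The scavenger receptor gene Cd36 was 25.2-fold lower, Gpr4 21.2-fold, Adam8 19.9-fold, Serpinb6b 18.9-fold, Pdia5 18.5-fold, P2ry14, a receptor for UDP-sugars, 16-fold and the chemokine receptor gene Cxcr3 14.9-fold. The brightest genes under the floor on the CD8+CX3CR1+ array were Ttc39a (at least 29.8-fold lower), Gcsam (at least 29.6-fold), Sema4f (at least 24.6-fold), Gp2, a glycoprotein gene (at least 24.3-fold), and Rab32 (at least 17.4-fold).

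**Figure D2:**
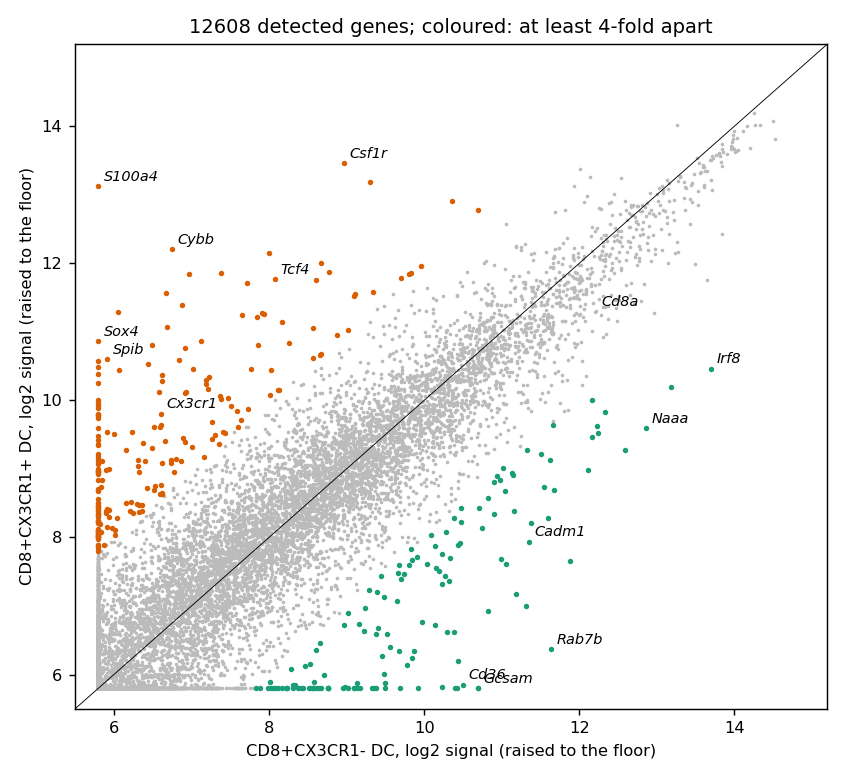
Log2 MAS5 signal of the 12608 detected genes on the CD8+CX3CR1+ array (vertical axis) against the CD8+CX3CR1- array (horizontal axis), 1 point per gene, with values under the floor raised to it and the line of equal signal in black. Orange points are the 210 genes at least 4-fold higher and green points the 145 genes at least 4-fold lower on the CD8+CX3CR1+ array, and Cd8a lies near the line of equal signal.

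The lists of DC subset markers separated the CD8+ arrays. Of 20 detected genes of the CD8 DC list, also called the cDC1 list, 13 were at least 4-fold lower on the CD8+CX3CR1+ array and 0 were higher, with a median log2 difference of -3.10, while the medians of random lists matched on signal lay between -0.30 and 0.30 in their central 95%. Its members with the largest differences were Rab7b, Gcsam, Cd36 and Tlr3, a receptor for double-stranded RNA (13.6-fold lower, 98.4 against 1338). Of 15 detected genes of the CD4 and CD11b DC list, also called the cDC2 list, 11 were at least 4-fold higher and 0 were lower, with a median of 3.16 (random lists -0.31 to 0.34), and of 1.30 to 3.74 under the other settings, lowest with probe sets averaged. S100a4 and Csf1r were among them, with the cytokine gene Ltb (20.8-fold) and the lectin gene Cd209a (at least 17.9-fold). Of 17 detected C-type lectins, a group of carbohydrate-binding receptors, 9 were at least 4-fold higher and 1 was lower, with a median of 2.30 (random lists -0.21 to 0.29). Besides Cd209d and Cd209a, Cd209e was at least 17.1-fold and Clec4a3 at least 15.3-fold higher.

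Genes of the plasmacytoid DC list had a median log2 difference of 1.49 (random lists -0.24 to 0.30), and 3 of 17 detected members were at least 4-fold higher on the CD8+CX3CR1+ array. These were Klra17, Spib and Tcf4, which encodes the transcription factor E2-2 (12.9-fold, 3489 against 270). Atp1b1 was 265 against 77.7. Without the members that also stand in another list the median was 0.42, inside the random range of -0.39 to 0.45. Of 19 detected DC transcription factors, 5 were at least 4-fold higher and 2 lower, with a median of 0.69 (random lists -0.32 to 0.32). Irf4 was at least 15.8-fold higher on the CD8+CX3CR1+ array (880 against a value under the floor), with Spib and Tcf4, and Irf8 was 9.43-fold lower (1409 against 13285). With a gene's probe sets averaged, the median of the transcription factors was 0.21, inside the random range of -0.28 to 0.26.

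Among the lists for other cell types, 2 of 13 red pulp macrophage genes were at least 4-fold higher on the CD8+CX3CR1+ array, with a list median of 1.06 (random lists -0.23 to 0.29), and of 0.99 to 1.78 under the other settings. C1qb, a chain of the complement component C1q, was 12.4-fold higher (742 against 60), Adgre1, which encodes F4/80, was 4.04-fold higher, and C1qa and C1qc were 197 and 185 against values under the floor. Of 12 monocyte genes, 2 were at least 4-fold higher and 1 lower, with a median of 0.79 (random lists -0.39 to 0.38). The members higher were Csf1r and Ms4a6c (8.96-fold), and Treml4 was 10.8-fold lower (196 against 2124). Without members shared with other lists the monocyte median was 0.15, inside the random range of -0.45 to 0.48. In the B cell list, 1 of 10 genes passed 4-fold, Cd79b, which was at least 10.6-fold higher, and the median of 0.09 lay inside the random range. In the natural killer (NK) cell list, 1 of 7 genes passed, Klrd1. The NK median of 0.46 lay at the edge of the random range of -0.47 to 0.45, and past it in 1 of 8 other settings. Of 7 genes of early lymphocytes and immunoglobulin recombination, 1 passed, the interleukin 7 receptor gene Il7r (5.23-fold higher, 559 against 107), with a median of 0.35 inside the random range, though outside it after quantile normalization (0.48). None of the 5 T cell, 4 neutrophil and 3 erythroid and platelet genes detected passed 4-fold, and their medians were 0.09, -0.28 and -0.04, each inside the random range.

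Genes of antigen presentation by MHC class I and of cross-presentation had a median of -0.49 (random lists -0.39 to 0.19). The proteasome subunit genes Psmb8 (1530 against 4194) and Psmb9 (2808 against 7126) and Pdia3 (1035 against 2890) were lower on the CD8+CX3CR1+ array by less than 4-fold, and the 1 of 17 members past 4-fold, Cybb, was higher. Under the other settings this median was -0.76 to -0.31, and with probe sets averaged it was -0.36, inside the random range of -0.37 to 0.25. The 11 genes of MHC class II presentation had a median of 0.19, inside the random range of -0.47 to 0.24 but above it in 4 of 8 other settings, and 1, H2-DMb2, was 4.06-fold higher. Interferon-stimulated genes had a median of 0.73 (random lists -0.28 to 0.42; 0.38 to 1.08 under the other settings) and 0 of 17 passed 4-fold. Cell cycle genes had a median of -0.70 (random lists -0.35 to 0.32) with 0 of 19 past 4-fold, and the mitotic genes Ccnb2 and Cdk1 were 189 against 634 and 296 against 825. Immediate early and dissociation stress genes had a median of -0.39 (random lists -0.33 to 0.32; -0.65 to -0.44 under the other settings), and 1 of 16, Jun, was 4.31-fold higher.

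The other groups had medians inside the random range. Of 13 costimulation and maturation genes, which had a median of -0.39 that lay below the random range in 4 of 8 other settings, 1 passed, Cd86, whose product is a ligand of CD28 and CTLA-4 and which was 9.93-fold lower (312 against 3099). Of 11 Toll-like receptors, Tlr3 was lower while Tlr1 was 9.91-fold and Tlr5 at least 4.70-fold higher, and the list median was 0. Of 10 chemokine receptors, with a median of -0.01 (1.04, above the random range, without members of other lists), Cxcr3 and Xcr1 (at least 9.31-fold) were lower, and Ccr6 (at least 6.15-fold) and Ccr1 (at least 4.92-fold) were higher. Among 8 Notch targets, 1 passed, Dtx1, at least 13.9-fold higher, and the median was 0.26, above the random range in 1 of 8 other settings. The sex-linked list had a median of 0. Xist, which is expressed from the inactive X chromosome, was between 2382 and 4965 on all 4 arrays, and the Y-linked Eif2s3y between 234 and 301. Uty, also Y-linked, lay above the floor on the DN array alone (79.7). The further Y-linked member of the list on the platform was detected on no array.

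As a measure of probe error, the standard deviation of a gene's log2 difference over its probe sets had a median of 0.33 in this comparison. Its root mean square over genes was 0.47. For 150 of the 165 called genes with a further probe set above the floor, every such probe set gave the same direction. With a gene's probe sets averaged, the differences of Cx3cr1, Jun, Il7r, Ccr1, Irf4, Dtx1, Slc2a3 and Sox4 were under 4-fold. So were those of Tlr3, Dtx1 and Slc2a3 without _x, _s and _a probe sets, and those of Adgre1, Jun and H2-DMb2 with another scaling.

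The CD8+CX3CR1- and CD4+ arrays were compared as a reference for the difference between CD8+ and CD4+ DCs. The CD8+CX3CR1- array was at least 4-fold higher for 149 genes and lower for 227. Naaa, an acid amidase gene, was 32.7-fold higher (7460 against 228), Gcsam 22.9-fold, Tlr3 22.6-fold, the transcription factor gene Irf8 21.5-fold (13285 against 617), Sh3pxd2b 21.2-fold, Cd24a 19.4-fold, the adhesion molecule gene Cadm1 16.6-fold and Sema4f 15.6-fold. The brightest genes under the floor on the CD4+ array were Cd8a (at least 85.1-fold higher), Pdia5 (at least 67.4-fold), Rab7b (at least 57.3-fold), P2ry14 (at least 41.8-fold) and Ttc39a (at least 29.8-fold). On the other side, Cybb was 33.1-fold lower on the CD8+CX3CR1- array, Fcer1g 31.1-fold, the transglutaminase gene Tgm2 28.5-fold, Csf1r 27.9-fold, Dennd3 26.0-fold, the sialyltransferase gene St8sia6 22.9-fold, Adgre1 21.4-fold and Ddit4, an inhibitor of mTORC1 signalling, 21.0-fold. S100a4 (at least 130-fold), Sirpb1a (at least 62.3-fold), Dtx1 (at least 52.0-fold), Clec4a3 (at least 26.0-fold) and Ifit3 (at least 20.3-fold) were the brightest genes under the floor on the CD8+CX3CR1- array.

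By list, 14 of the 20 CD8 DC genes were at least 4-fold higher on the CD8+CX3CR1- array than on the CD4+ array and 0 were lower, with a median log2 difference of 3.38 (random lists -0.40 to 0.31). Of the 15 genes of the CD4 and CD11b DC list, 11 were at least 4-fold lower and 0 higher, with a median of -2.60 (random lists -0.40 to 0.35), and of -4.14 to -2.37 under the other settings. Of the interferon-stimulated genes, 7 of 17 were at least 4-fold lower on the CD8+CX3CR1- array and 0 higher, with a median of -1.87 (random lists -0.47 to 0.35). Ifit3 was at least 20.3-fold, Rtp4 at least 18.9-fold, Oas2 at least 12.6-fold and Oas1a 11.1-fold lower. The CD4+ array of this comparison is the array with the highest Gapdh 3'/5' ratio (11.8) and share of probe sets above the floor (47.6%). The interferon-stimulated list was, however, also lower on the CD8+CX3CR1- array than on the DN array (median -1.26), which had the lowest ratio (7.56). Monocyte genes had a median of -1.35 (random lists -0.42 to 0.43) with 5 of 12 at least 4-fold lower and 2 higher. Csf1r and Ms4a6c (5.55-fold) were among the lower ones, and Cd14 (5.53-fold) and Treml4 (5.32-fold) were the higher ones.

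C-type lectins had a median of -0.78 (random lists -0.44 to 0.19), and of -2.47 to -0.43 under the other settings, with 5 of 17 lower, Clec4a3, Clec4a2 (at least 20.1-fold) and Clec4n (at least 15.6-fold) among them, and 1 higher, Cd207, which encodes langerin (at least 13-fold). Toll-like receptors had a median of -0.58 (random lists -0.53 to 0.33), and of -0.95 to -0.57 under the other settings, with Tlr1 (15.5-fold), Tlr7 (at least 8.12-fold) and Tlr5 (at least 6.07-fold) lower and Tlr3 higher. The MHC class I and cross-presentation genes had a median of 0.47 (random lists -0.29 to 0.37) and a mean of -0.04, so that median and mean differed in sign, and the 1 of 17 past 4-fold, Cybb, was lower. Chemokine receptors had a median of 0.44 (random lists -0.47 to 0.35), outside the random range in 5 of 8 other settings, and Xcr1 (at least 9.31-fold) and Cxcr3 (7.93-fold) were higher while Ccr6 was at least 19.6-fold lower.

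The other lists had medians inside the random range or at its edge. Those for plasmacytoid DCs (-0.36), red pulp macrophages (-0.36), DC transcription factors (-0.28), B cells (-0.47) and early lymphocytes (-0.42) lay below 0, with Spib (9.57-fold), Cd22 (9.36-fold), Cd79b (at least 7.21-fold), C1qb (5.97-fold) and Irf4 (at least 5.47-fold) lower on the CD8+CX3CR1- array. Of these, the red pulp macrophage list lay below the random range in 4 of 8 other settings, the transcription factors in 3, the plasmacytoid DC list in 2 and the B cell list in 1. MHC class II genes had a median of -0.38, equal to the lower limit of the random range and below it in 7 of 8 other settings, with 0 of 11 past 4-fold. Costimulation and maturation genes (0.13, mean -0.19) had 3 of 13 lower, namely Pdcd1lg2 (at least 8.20-fold), Relb (4.94-fold) and Cd274 (4.71-fold). Medians were 0.30 for cell cycle genes, 0.05 for immediate early genes (mean -0.08), 0.03 for Notch targets (mean -0.59), -0.06 for neutrophil genes and 0 for T cell, NK cell, erythroid and platelet, and sex-linked genes. Klrk1 was 4.44-fold higher and Klrd1 11.3-fold lower in the NK list. The median of this list lay below the random range without _x, _s and _a probe sets (-1.01).

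The probe set standard deviation had a median of 0.39 and a root mean square of 0.55. Of 169 called genes with a further probe set above the floor, 146 had every such probe set in the same direction. With probe sets averaged, Cd4, Tlr7, Clec4a2, Rtp4 and Irf4 were less than 4-fold apart. So were Dtx1 and Tlr3 without _x, _s and _a probe sets.

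**Figure D3:**
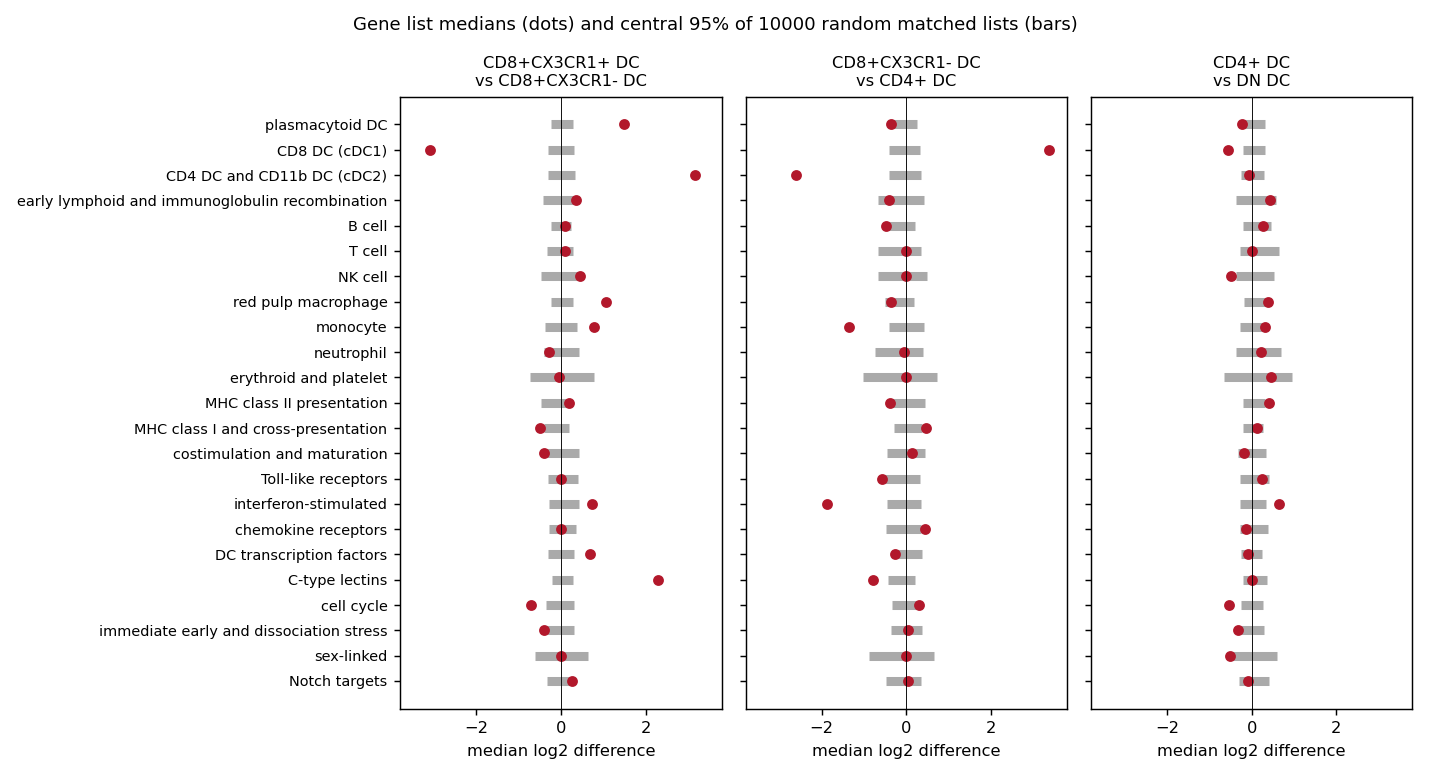
Median log2 difference of each of the 23 gene lists (dots) in the 3 main comparisons, 1 panel each, with grey bars for the central 95% of 10000 random lists matched on signal. The CD8 DC list lies at -3.10 and the CD4 and CD11b DC list at 3.16 in the first panel, and at 3.38 and -2.60 in the middle panel.

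CD4+ and DN DCs were much closer. The CD4+ array was at least 4-fold higher for 9 genes and lower for 23. The genes higher on the CD4+ array above the floor on both arrays were the apolipoprotein gene Apoe (6.33-fold, 1397 against 221), Cd4 (6.00-fold), C1qb (5.10-fold), Amdhd2 (5.05-fold) and the zinc transporter gene Slc39a13 (4.09-fold). Fbxw22 (at least 5.48-fold), the chemokine gene Cxcl1 (at least 4.24-fold), Tex264 (at least 4.14-fold) and Fpr2, a formyl peptide receptor gene (at least 4.08-fold), were under the floor on the DN array. Ahnak, which encodes a very large scaffold protein, was 14.3-fold lower on the CD4+ array (92.5 against 1320), Naaa 8.71-fold, Cd24a 8.16-fold, Irf8 7.86-fold (617 against 4847), Rnf185 6.38-fold, Sh3pxd2b 5.15-fold, Rassf4 4.83-fold and the galectin gene Lgals1 4.27-fold. Pdia5 (at least 8.82-fold), Rab7b (at least 7.45-fold), P2ry14 (at least 7.01-fold), Trim26 (at least 4.98-fold) and Rtn4rl1 (at least 4.91-fold) were under the floor on the CD4+ array. The further probe sets of Rassf4 (log2 differences 0.11 to 0.94) and Trim26 (0.17) gave the opposite direction.

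Of the 20 CD8 DC genes, 4 were at least 4-fold lower on the CD4+ array than on the DN array, Naaa, Cd24a, Irf8 and Rab7b, and 0 were higher, with a median of -0.57 (random lists -0.22 to 0.31), and of -1.57 to -0.37 under the other settings. Cd8a was under the floor on the CD4+ array and 130 on the DN array. The CD4 and CD11b DC list had a median of -0.07 (mean 0.07), inside the random range, with 0 of 15 past 4-fold. Interferon-stimulated genes had a median of 0.65 (random lists -0.27 to 0.34) and 0 of 17 past 4-fold, with Ifit3 at 1133 against 427 and Usp18 at 645 against 241, and the CD4+ array again had the higher Gapdh 3'/5' ratio (11.8 against 7.56). Cell cycle genes had a median of -0.54 (random lists -0.26 to 0.27) and immediate early genes one of -0.34 (random lists -0.25 to 0.29; -0.54 to -0.27 under the other settings), with 0 genes past 4-fold in either. MHC class II genes had a median of 0.40 (random lists -0.22 to 0.31), but of 0.11 after quantile normalization, inside its random range of -0.26 to 0.22. NK cell genes had a median of -0.48 (random lists -0.37 to 0.53), outside the random range in 6 of 8 other settings. Plasmacytoid DC genes had one of -0.23 (random lists -0.22 to 0.32), outside in 4 of 8. Of 13 red pulp macrophage genes, 1 passed, C1qb, and C1qc and C1qa were 206 and 203 on the CD4+ array and under the floor on the DN array, with a list median of 0.38 inside the random range but above it in 4 of 8 other settings.

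In the remaining lists, Irf8 was the 1 DC transcription factor past 4-fold (list median -0.09). Medians inside the random range, with 0 genes past 4-fold, were 0.30 for monocyte (above the range in 4 of 8 other settings), 0.26 for B cell, 0.43 for early lymphocyte, 0.22 for neutrophil, 0.46 for erythroid and platelet, 0.23 for Toll-like receptor, 0.13 for MHC class I and cross-presentation, -0.18 for costimulation (mean 0.05), -0.13 for chemokine receptor and -0.08 for Notch target genes, and 0 for T cell genes and C-type lectins. The sex-linked list had a median of -0.52 over 3 genes, just outside the random range of -0.50 to 0.60, and outside it in 3 of 6 other settings. That median is the value of Uty, a bound with the CD4+ array under the floor. Xist (-0.73) and the Y-linked Eif2s3y (0.18) differed in opposite directions, so the list did not shift as a whole. The probe set standard deviation had a median of 0.36 and a root mean square of 0.50. Of 15 called genes with a further probe set above the floor, 12 had every such probe set in the same direction. With probe sets averaged, Cd4, Rab7b, C1qb, Ahnak, Rnf185, Sh3pxd2b, Rassf4, Lgals1, Cxcl1, Trim26 and Rtn4rl1 were less than 4-fold apart. So were Rnf185 and Cxcl1 without _x, _s and _a probe sets. With the floor at the 75th percentile 50 genes were higher and 39 lower.

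The remaining pairs set each CD8+ array against the other profiles. List medians were recomputed under the other settings for the main comparisons only, so those given here carry no such check. The interferon-stimulated list was lower on the CD8+CX3CR1+ array than on the CD4+ array, with a median of -1.13 (random lists -0.31 to 0.33) and 5 of 17 genes at least 4-fold lower, and had a median of -0.67 against the DN array (random lists -0.22 to 0.30) with 1 lower. The plasmacytoid DC list was higher on the CD8+CX3CR1+ array than on the CD4+ array, with a median of 0.86 (random lists -0.30 to 0.23) and 4 of 17 genes at least 4-fold higher, and had a median of 0.54 against the DN array (random lists -0.18 to 0.21) with 1 higher. Between the CD8+ arrays this list fell inside the random range without members of other lists. How far these 2 medians rest on such shared members was not tested. Against the DN array, cell cycle genes had a median of -0.89 (random lists -0.21 to 0.22) with 0 of 19 past 4-fold, and the CD8 DC list one of -0.48 (random lists -0.21 to 0.21) with 2 of 20 at least 4-fold lower. The other lists outside the random range against the DN array were immediate early genes (-0.51), Toll-like receptors (-0.40), early lymphocyte genes (0.43), DC transcription factors (0.31), C-type lectins (0.26) and MHC class II genes (0.16). Against the CD4+ array they were Toll-like receptors (-0.47), costimulation genes (-0.46), cell cycle genes (-0.38), immediate early genes (-0.37) and DC transcription factors (0.41). Between the CD8+CX3CR1- and DN arrays, 93 genes were at least 4-fold higher and 162 lower, with 9 of 20 CD8 DC genes higher (median 1.78, random lists -0.26 to 0.28) and 10 of 15 genes of the CD4 and CD11b DC list lower (median -2.87, random lists -0.29 to 0.29). The other lists outside the random range in this pair were C-type lectins (-1.69), interferon-stimulated (-1.26), monocyte (-0.90), NK cell (-0.65) and MHC class I genes (0.54) and DC transcription factors (-0.28).

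Genes at least 4-fold above all 3 other arrays numbered 66 on the CD8+CX3CR1- array, 19 on the CD8+CX3CR1+ array, 1 on the CD4+ array, which was Cd4, and 0 on the DN array. On the CD8+CX3CR1- array these were led by Ttc39a, at least 29.8-fold above the next array, Cd207 (at least 13-fold), Fndc7 (at least 11.8-fold), the prostacyclin synthase gene Ptgis (at least 11.6-fold), Itgae, which encodes CD103 (10.7-fold), Cadm1 (10.7-fold), Igf2r (at least 10.3-fold) and Sema4f (10.2-fold). On the CD8+CX3CR1+ array they were led by the transcription factor gene Sox4, 13.4-fold above the next array, the oxysterol hydroxylase gene Cyp7b1 (10.3-fold), Lefty1, a Nodal antagonist (8.17-fold), Kdr, a receptor for vascular endothelial growth factor (7.64-fold), Cd209d (7.46-fold), Xkrx (at least 6.07-fold), Pdzd4 (5.42-fold) and the receptor phosphatase gene Ptprf (5.33-fold). With probe sets averaged, 9 genes were left on the CD8+CX3CR1+ array and 0 on the CD4+ array.

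**Figure D4:**
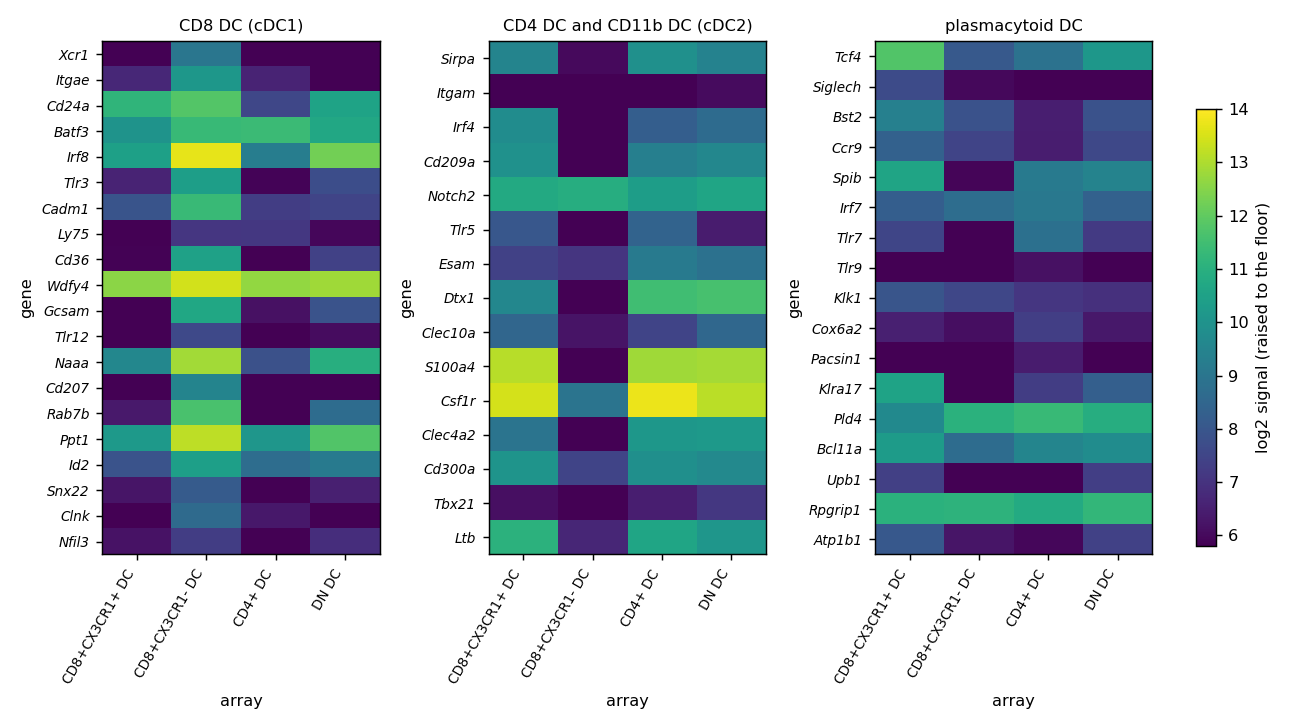
Log2 MAS5 signal (colour scale, values under the floor raised to it) of the detected genes of the CD8 DC, CD4 and CD11b DC, and plasmacytoid DC lists on the 4 arrays, 1 row per gene and 1 column per array. Irf8 is brightest on the CD8+CX3CR1- array (13285) and next brightest on the DN array (4847), S100a4 is under the floor on the CD8+CX3CR1- array alone, and Tcf4 is brightest on the CD8+CX3CR1+ array (3489).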

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

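The comparisons of named genes leave out 10092 probe sets that have no gene symbol or several. Of these, 60 were at least 4-fold apart between the CD8+CX3CR1+ and CD8+CX3CR1- arrays, 42 higher and 18 lower, and 59 between the CD8+CX3CR1- and CD4+ arrays, 20 higher and 39 lower. Between the CD4+ and DN arrays there were 4. They were singled out because they carry a signal in data that the comparisons do not use, and no explanation was tested for them.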

How the results depend on the processing

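The 16 counts of genes at least 4-fold apart or 4-fold highest stayed within 1.5 times of their values under quantile normalization and equal medians. The same held without _x, _s and _a probe sets. Under the other alternatives, 31 values moved further. Without a floor all 16 grew, because weak signals then give large ratios. The counts higher and lower were then 1659 and 1521 for CD8+CX3CR1+ against CD8+CX3CR1-, 1403 and 2226 for CD8+CX3CR1- against CD4+, 1992 and 1218 for CD4+ against DN, 1220 and 1879 for CD8+CX3CR1+ against CD4+, 1462 and 1350 for CD8+CX3CR1+ against DN, and 1643 and 1722 for CD8+CX3CR1- against DN. The 4-fold highest genes numbered 139 on the CD8+CX3CR1+, 235 on the CD8+CX3CR1-, 360 on the CD4+ and 166 on the DN array. With the floor at the 75th percentile the counts were 50 and 39 for CD4+ against DN, 93 and 96 for CD8+CX3CR1+ against CD4+, and 57 and 31 for CD8+CX3CR1+ against DN, with 7 genes highest on the CD4+ array. At the 95th percentile, 13 genes were lower on the CD4+ than on the DN array and 23 higher on the CD8+CX3CR1+ than on the DN array. With probe sets averaged, 128 genes were higher on the CD8+CX3CR1+ than on the CD8+CX3CR1- array, 31 higher than on the CD4+ array and 21 higher than on the DN array, 107 were lower on the CD8+CX3CR1- than on the DN array, and 9 were highest on the CD8+CX3CR1+ and 0 on the CD4+ array. The cause was not tested for the averaged probe sets.

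The share of higher genes among those called between the CD4+ and DN arrays was 28.1%, against 56.2% with the floor at the 75th percentile, 62.1% without a floor and 39.3% with probe sets averaged, so that its direction rests on the floor. Of 28 list medians outside the random range in the main comparisons, 18 lay outside it on the same side under every alternative run for them and 10 did not. Of the 28, 19 moved by over 1.5 times under at least 1 alternative. The median of the CD4 and CD11b DC list ranged from 1.30 to 3.74 for CD8+CX3CR1+ against CD8+CX3CR1- and from -4.14 to -2.37 for CD8+CX3CR1- against CD4+, that of the CD8 DC list from -1.57 to -0.37 for CD4+ against DN, and that of the C-type lectins from -2.47 to -0.43 for CD8+CX3CR1- against CD4+. Between the CD8+CX3CR1+ and CD8+CX3CR1- arrays, interferon-stimulated genes ranged from 0.38 to 1.08 and red pulp macrophage genes from 0.99 to 1.78. Toll-like receptors ranged from -0.95 to -0.57 for CD8+CX3CR1- against CD4+. Of 41 medians inside the random range, 13 lay outside under at least 1 alternative. No called list median or named gene changed sign. No array could be left out, since each group has 1. Under the floor of 55.7 neither a level nor an order of genes can be read.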

Other observations

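Several groups of genes with related names, singled out after the data were seen, had members far lower or higher on the CD8+CX3CR1- array, and no enrichment test was run on them. Of all 12608 detected genes, 588 had a 4-fold range over the arrays, with 325 lowest and 205 highest on the CD8+CX3CR1- array. Of 9 detected Ms4a genes, which encode membrane-spanning proteins, 5 had such a range and were lowest on the CD8+CX3CR1- array, with Ms4a4c at 121 there and 1747 on the CD8+CX3CR1+ array, and Ms4a6b at 230 and 2372. The same held for 3 of 9 S100a genes, with S100a6 at 140 and 1874, for 3 of 5 Cd300 genes, with Cd300lf at 122 and 1112, and for both detected Tmem176 genes, with Tmem176b at 631 and 9303. Of 6 genes of the NADPH oxidase and its proton channel, 3 had such a range. Cybb and Hvcn1 were lowest on the CD8+CX3CR1- array. Ncf4 was instead lowest on the CD8+CX3CR1+ array, at 382 against 1811 on the CD8+CX3CR1-, 1821 on the CD4+ and 1573 on the DN array.

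In the other direction, 3 of 17 serpin genes had a 4-fold range and were highest on the CD8+CX3CR1- array, with Serpinb9 at 1234 there and 174 on the CD8+CX3CR1+ array. The same held for 2 of 19 genes with names that begin with Tub, both tubulin genes, with Tubb2a at 935 and 81.5. Of 17 chemokine genes, 4 had such a range. Cxcl9 was 4430 and 506 and Cxcl16 1665 and 344 on the CD8+CX3CR1- and CD8+CX3CR1+ arrays, Ccl9 was under the floor and 874, and Cxcl1 was highest on the CD4+ array.

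The tests that follow were chosen after their results had been seen, except the one of other spleen macrophages. The first pattern is the level of CD8 DC genes on the DN array, where Irf8, Naaa and Cd24a were above the CD4+ array. CD8+CX3CR1+ cells carried into the DN sort cannot account for the 7 genes at least 2-fold higher on the DN array than on both the CD4+ and CD8+CX3CR1+ arrays. If CD8+CX3CR1- cells carried into the DN sort were the source, 1 share of such cells, mixed with the CD4+ signal, should give the DN signal of the 14 list genes at least 4-fold higher on the CD8+CX3CR1- than on the CD4+ array. At the share that left the fewest genes apart, 8%, 4 of the 14 (28.6%) were still over 2-fold from the mixture. After values under the floor were raised to it, Irf8 (log2 1.57), Cd24a (1.72) and Naaa (1.30) lay above the mixture. Itgae (-1.69) lay below it, as did Cd8a (-1.61), which is not in the list. This choice of share favours carryover, and Ppt1 (0.995) and Cadm1 (-0.975) lay just inside the 2-fold limit. No single share of CD8+CX3CR1- cells thus gave the DN signal of all 14 genes within 2-fold. Carryover of such cells and expression of these genes by DN cells cannot be told apart, since a sort that removes CD8+ cells would favour carried cells with low CD8 and 3 of the genes within 2-fold, Xcr1, Cd207 and Clnk, lay under the floor on the DN array and could not have been farther from the mixture.

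The second pattern is the plasmacytoid DC list on the CD8+CX3CR1+ array. If plasmacytoid DCs carried into the CD8+CX3CR1+ sort were the source, most of the list should stand above the other arrays. Of 17 detected genes, 10 were highest on that array but 5 were at least 2-fold above the other 3 arrays, Tcf4, Siglech, Bst2, Spib and Klra17, while Pld4 (825 against 1917 to 2584) and Irf7 were lowest there. The sort for high CD11c should remove most plasmacytoid DCs, and the list shares 8 detected genes with other lists. A minority of such cells in the gate and expression of these genes by the CD8+CX3CR1+ cells themselves cannot be told apart, since the data hold no cell counts.

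The third pattern is C1q and Apoe, which were higher on the CD8+CX3CR1+ and CD4+ arrays than on the other arrays, with C1qb at 742 and 358 against 60 and 70.2 and Apoe at 1726 and 1397 against 523 and 221 (CD8+CX3CR1- and DN). If red pulp macrophages carried into both sorts were the source, Spic, Hmox1, Slc40a1 and Vcam1 should be higher too, but 0 of these 4 were at least 2-fold above the DN array on both, and Vcam1 was 291 and 142 against 109 on the DN array and 513 on the CD8+CX3CR1- array. Of other macrophage genes, Cd5l went with C1q, at 177 and 148 against values under the floor, and Adgre1 did so in part, at 3068 on the CD4+ array but 579 on the CD8+CX3CR1+ array against 1692 on the DN array. As 1 of the 4 lay at least 2-fold above the floor on both arrays, a small share of such cells might be missed, although the sort for high CD11c should remove most macrophages; for other spleen macrophages carried into both sorts, 0 of 5 markers (Marco, Siglec1, Timd4, Vsig4 and Cd209b) were at least 2-fold higher, and 1, Cd209b, lay above the floor on at least 1 of these arrays. These sources and expression of C1q and Apoe by the DCs cannot be told apart, because most of the markers lie near or under the floor.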
